A study of Homo sapiens with 14 samples.

How the data were processed

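Expression was measured in WI-38 fibroblasts on 14 Affymetrix arrays, 4 groups by dose. Per the labels' protocols, total RNA was column-purified, treated with DNase, checked for integrity and labelled by the manufacturer's protocol. The deposited values are linear intensity per probe set for 54675 probe sets, from 0.951 to 7569, with no missing values. Per the submitters' processing notes RMA was used; its version, background model, whether the arrays were processed together and the step back to a linear scale are not given in the sources used here. Medians per array ran from 4.86 to 5.49 and upper quartiles from 19.7 to 26.5, so the columns are close to each other but not equal. Summarised arrays give no counts, so their number, 3 or 4 per group, limits the precision.

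Groups were taken from the sample titles. For the 0.1 and 0.5 µM samples the description field names the vehicle, while the title, the source name and the design text name BPDE; the titles were followed. The design had foreseen log2 values, or log2(value + 1) for linear ones, and the latter was used. This scale understates changes of low genes.

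Probe sets were named through the platform annotation: 41091 had 1 gene, 1801 several, 11721 none and 62 were controls. Only probe sets with 1 gene were used, and for each gene the probe set with the highest mean over the 14 arrays, giving 19775 genes (10523 had more than 1 probe set). By gene ID, 19735 genes matched a RefSeq gene table of GRCh38.p14, used for names and gene lengths (19731 genes); the array's build is not given, so no coordinates are reported. Some members of the 27 gene lists did not match a gene and are not used here.

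Each dose was compared with DMSO, and 0.5 with 0.1 µM and 1 with 0.5 µM, in limma 3.58.1 (R 4.3.3), with 1 model over all 14 arrays, two-sided tests and Benjamini-Hochberg adjustment over all genes at 0.05. The trend was a straight line in dose. The lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over lists of at least 5 members. fry tests whether a list moves on balance one way and does not compare it with other genes. Groups, tests, lists, most alternatives and the naming rule were fixed before the data were examined. The rule took, per dose, the 8 highest and 8 lowest called genes with every array outside the DMSO range, up to 3 called members per list (or the member with the smallest adjusted p), the 4 highest and 4 lowest per comparison between doses and for the trend, and CDKN1A, MDM2, CYP1A1, CYP1B1 and GAPDH. Genes with placeholder symbols were skipped, and the text names part of the set. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

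The limma step was tested on simulated data for 19775 genes, 200 of them changed, over 5 draws. With 1 pooled spread per gene, 2-fold changes were recovered for 74.7, 72.5 and 77.3% of changed genes at 0.1, 0.5 and 1 µM, with 8.23, 6.33 and 4.57% false among those called. With each group's own spread, false calls stayed at 5.28 and 3.18% at 0.1 and 0.5 µM but were 56.5% at 1 µM; with only the 1 µM and DMSO arrays in the fit they were 12.4%, with 56.3% of 2-fold changes recovered. The model over all arrays therefore understates the error at 1 µM, so counts of list members called over all genes at that dose are given beside those from the fit of its own groups. Counts adjusted over a list alone come only from the model over all arrays. In 5 draws per dose, camera found the 1 shifted list among 27 each time and called 0 others. Those genes were drawn independently and the lists at random, so the preset correlation was not tested on lists whose members move together. In the real arrays the estimated correlation was 0.557 for the G2/M list and 0.479 for the p53 targets. Each estimate was the same at every dose, so at 0.1 and 0.5 µM it also includes the spread between the 1 µM arrays. An estimate without the 1 µM arrays was not made.

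Replicate numbers were tested for pairing through the correlation of deviations from group means over genes, which are not independent replicates. Same-numbered DMSO and 1 µM arrays correlated at 0.324, 0.332, 0.163 and 0.329, all above 0.1, so the numbers were taken to pair these groups; the pairing comes from the data, not the labels. DMSO and 0.5 µM arrays (0.097, -0.099 and -0.028) were not taken as paired. DMSO and 0.1 µM arrays correlated at 0.106, 0.092 and 0.074 over all genes, not all above 0.1 but each highest with its own number, and at 0.221, 0.155 and 0.143 over genes with a mean log2 level of at least 5, so their pairing is left open.

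The alternatives were a replicate block, each array left out in turn, a filter on dim genes, quantile normalization again, median centring, only the compared groups in the fit, a trended robust prior, array weights, other choices of probe set, a 1.5-fold minimum, the rank of the dose and other list tests. Pseudocounts of 0 and 16, and leaving out 1 µM arrays 2 and 3, were added after seeing the data. Sex-linked transcripts were left out of the naming.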

Results

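WI-38 cells are an established line of normal human lung fibroblasts, the cells that lay down connective tissue. Anti-BPDE is benzo[a]pyrene diol epoxide, the reactive metabolite of the smoke carcinogen benzo[a]pyrene, which forms bulky adducts on DNA. Cells were taken 24 h after exposure to DMSO vehicle (4 arrays), 0.1 µM BPDE (3 arrays), 0.5 µM BPDE (3 arrays) or 1 µM BPDE (4 arrays), and total RNA was measured on Affymetrix arrays. The series asks how expression at each dose differs from the vehicle. The labels call the replicates biological, with nothing on separate cultures or days, so the p-values measure the spread between these samples. Levels are log2(intensity + 1), changes are differences of group means on that scale with the SE of the limma fit, and 19775 genes were tested. The number of arrays limits the precision. Median intensity per array ran from 4.86 to 5.49.

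The spread between arrays differed greatly between groups. Over 6938 genes with a mean log2 level of at least 5, the median SD was 0.187 in DMSO (n = 4), 0.061 at 0.1 µM (n = 3), 0.073 at 0.5 µM (n = 3) and 0.378 at 1 µM (n = 4). The lowest correlation between arrays of one group was 0.996 at 0.1 µM, 0.993 at 0.5 µM, 0.963 in DMSO and 0.833 at 1 µM. On the first principal component, which held 55.5% of the variance, arrays 2 and 3 at 1 µM lay at 63.9 and 48.5, and arrays 1 and 4 at -15.6 and -1.06.

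At 0.1 µM, genes of cell division were lower than in DMSO. Of 46 targets of the tumour suppressor p53, 9 rose, though the test of this list gave adjusted p = 0.0973 with an estimated correlation. PLK1, a mitotic kinase, fell by 2.05 ± 0.19 on the log2 scale (SE; adjusted p = 2.47e-04). BLM, a helicase of recombination repair, fell by 1.19 ± 0.13 (adjusted p = 8.06e-04). The p53 target SPATA18, a protein of mitochondrial quality control, rose by 2.11 ± 0.26 (adjusted p = 0.00165), and CYFIP2, another p53 target, rose as well (adjusted p = 0.0032). NPTX1 rose most, by 3.01 ± 0.37 (adjusted p = 0.00154), with BMP2, a bone morphogenetic protein, at 2.37 ± 0.29 and DKK2, a secreted Wnt regulator, at 2.15 ± 0.23 (1 of its 2 probe sets had this sign). AK4, a mitochondrial adenylate kinase, fell by 2.99 ± 0.26 (adjusted p = 2.47e-04), and HAS2, a hyaluronan synthase, by 3.02 ± 0.60 (adjusted p = 0.0215, up to 0.118 with 1 array left out). At 1 µM NPTX1, BMP2, DKK2 and AK4 did not pass (log2 changes 0.25, 0.33, -0.45 and 0.43, limma adjusted p = 0.684, 0.478, 0.192 and 0.28). PLK1, BLM, SPATA18, CYFIP2 and HAS2 were called there in the same direction. For NPTX1, BMP2 and AK4, also called at 0.5 µM, a batch shared by the 0.1 and 0.5 µM arrays cannot be told apart from a response to lower doses.

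Of 51 measured genes of G2/M and mitosis, 37 fell and 0 rose at 0.1 µM (mean log2 change -1.54; camera adjusted p = 6.66e-60, and adjusted p = 0.0241 with an estimated correlation). Of 45 genes of G1/S and replication, 17 fell and 0 rose (mean -0.95; adjusted p = 0.0378 with an estimated correlation), and of 24 Fanconi anaemia and homologous recombination genes 3 fell (mean -0.47; adjusted p = 0.0386 with an estimated correlation). Among 46 p53 targets, 9 rose and 0 fell (mean 0.69; camera adjusted p = 1.51e-20, but adjusted p = 0.0973 with an estimated correlation). The p53 list shifted from DMSO by 0.686, 0.701 and 0.686 in 0.1 µM arrays 1, 2 and 3, with an SD of 0.086 in DMSO. Its estimated correlation also includes the 1 µM arrays, which differed from each other in this list. Adjusted over the list alone, 50 G2/M genes, 35 G1/S genes and 9 hypoxia and glycolysis genes fell, and 21 p53 targets, 4 cholesterol synthesis genes and 5 interferon-stimulated genes rose. CDKN1A, the p53-induced inhibitor of the cell cycle, stood at 10.57 ± 0.03 (SD, n = 3) against 9.63 ± 0.16 (SD, n = 4) in DMSO, a difference that did not pass in the fit of all arrays (adjusted p = 0.0986) but did with only these groups in the fit (adjusted p = 0.00133). MDM2, the p53-induced ubiquitin ligase, likewise had adjusted p = 0.25 (log2 change 1.15 ± 0.44 SE) and adjusted p = 3.81e-04 with only these groups. Of 25 genes of hypoxia and glycolysis, 4 fell and 0 rose (mean -0.40; adjusted p = 0.0173 with an estimated correlation). Of 18 cholesterol synthesis genes 1 rose (mean 0.38, estimated-correlation adjusted p = 0.0173), and of 32 interferon-stimulated genes 2 rose (mean 0.36, estimated-correlation adjusted p = 0.0241). By camera the hypoxia, cholesterol and interferon lists also passed at 0.5 µM but not at 1 µM. A batch shared by the 0.1 and 0.5 µM arrays cannot be told apart from a response to lower doses here either. GBP1, an interferon-induced GTPase, rose by 1.30 ± 0.17 (adjusted p = 0.00227). Histones, the unfolded protein response (down), targets of the aryl hydrocarbon receptor and nucleotide excision repair passed by camera at 0.1 µM, with 2, 2, 2 and 0 members called. With an estimated correlation they did not (adjusted p = 0.0731, 0.0731, 0.0973 and 0.312), nor did the receptor targets with the replicate number as a block (adjusted p = 0.0622).

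In all, limma called 482 genes at 0.1 µM, 265 higher and 217 lower; the lower genes were the more numerous after quantile normalization again (221 and 253), with a 1.5-fold minimum (186 and 190) and without 1 µM array 3 (337 and 362) or 0.1 µM array 3 (39 and 40). The count was 1589 with only these groups in the fit, and fell to 79, 87 and 105 without 0.1 µM arrays 3, 2 and 1. It was 170 and 290 without DMSO arrays 3 and 1, 301, 287 and 306 without 0.5 µM arrays 1, 2 and 3, and 771 without 1 µM array 1. The external poly-A control transcript dap, added during labelling, averaged 8.09 in the 0.1 µM arrays and read 6.33 to 7.33 in DMSO.

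At 0.5 µM, histone genes were higher and mitotic genes lower than in DMSO. Of 46 p53 targets 25 rose, though the test of this list gave adjusted p = 0.153 with an estimated correlation. The p53 list shifted from DMSO by 0.881, 0.957 and 1.041 in 0.5 µM arrays 1, 2 and 3, with an SD of 0.086 in DMSO. Its estimated correlation, 0.479 at every dose, also includes the 1 µM arrays, where the shifts were 0.917, 0.106, 0.074 and 1.07. How much those arrays add to it was not tested. ATF3, a stress-induced transcription factor, rose by 4.13 ± 0.37 (SE; adjusted p = 3.85e-05). SAT1, which acetylates polyamines, rose by 3.24 ± 0.23 (adjusted p = 8.11e-06), and RRAD, a small GTPase, by 3.59 ± 0.27 (adjusted p = 9.95e-06). TTK, a kinase of the spindle checkpoint, fell by 3.58 ± 0.17 (adjusted p = 4.17e-07). CCNB1, the mitotic cyclin B1, fell by 3.77 ± 0.53 (adjusted p = 7.98e-04). The largest rise was in RNA45SN5, the ribosomal RNA precursor, at 4.53 ± 0.56 (adjusted p = 3.89e-04). The 28S ribosomal RNA control probe set was also higher, 9.45 to 10.04 against 6.17 to 8.32 in DMSO.

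Among 46 p53 targets, 25 rose and 0 fell at 0.5 µM (mean 0.96; camera adjusted p = 2.32e-17, but adjusted p = 0.153 with an estimated correlation). ACER2, a ceramidase, rose by 3.02 ± 0.39 and TP53INP1 by 2.67 ± 0.47. CDKN1A rose by 1.00 ± 0.27 (adjusted p = 0.031, up to 0.111 with 1 array left out), and MDM2 did not pass (adjusted p = 0.173), though it did with only these groups in the fit (adjusted p = 1.88e-04). Of 51 G2/M genes, 46 fell and 0 rose (mean -2.21; adjusted p = 0.0433 with an estimated correlation), and of 45 G1/S genes 21 fell (mean -0.94; adjusted p = 0.0943 with an estimated correlation). POLE2, a subunit of DNA polymerase epsilon, fell by 2.71 ± 0.15. Of 24 Fanconi anaemia and homologous recombination genes, which repair DNA crosslinks and breaks, 10 fell and 0 rose (mean -0.74; adjusted p = 0.0433 with an estimated correlation). Of 24 nucleotide excision repair genes, which remove bulky adducts, 1 rose and 1 fell (mean 0.04; camera adjusted p = 0.456); at 1 µM 1 rose and 3 fell (mean -0.13; camera adjusted p = 0.481), or 0 and 0 with only these groups in the fit. The list shifted by 0.113, -0.447, -0.278 and 0.09 in 1 µM arrays 1, 2, 3 and 4, with an SD of 0.025 in DMSO. The 1 µM mean therefore averages shifts of opposite sign.

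Of 42 replication-dependent histone genes, 12 rose and 0 fell at 0.5 µM (mean 0.69; adjusted p = 0.00445 with an estimated correlation). H1-2, a linker histone, rose by 2.48 ± 0.24 (adjusted p = 6.45e-05). Of 24 immediate early genes, 9 rose and 2 fell (mean 0.71; adjusted p = 0.0433 with an estimated correlation), among them FOS at 3.23 ± 0.64 and FOSB at 2.82 ± 0.47. Of 12 targets of the aryl hydrocarbon receptor, the sensor of polycyclic hydrocarbons, 3 rose (mean 0.69; adjusted p = 0.0455 with an estimated correlation). CYP1B1 rose by 2.92 ± 0.40 (adjusted p = 7.33e-04), and CYP1A1, at a low level of 2.92 against 2.37 in DMSO, by 0.54 ± 0.12 (adjusted p = 0.0125, up to 0.0646 with 1 array left out). COL1A1 and COL3A1, which encode collagens I and III, fell by 1.54 ± 0.17 and 1.73 ± 0.27. Among 86 genes of mitochondrial oxidative phosphorylation, 24 rose and 1 fell (mean 0.17; camera adjusted p = 1.6e-06, but adjusted p = 0.272 with an estimated correlation). Of the hypoxia and glycolysis genes, 6 of 25 fell (mean -0.36; adjusted p = 0.0455 with an estimated correlation), and of 18 cholesterol synthesis genes 3 rose (mean 0.31; adjusted p = 0.0469 with an estimated correlation). The unfolded protein response (3 rose, 5 fell), chromatin modifiers (2 rose, 4 fell) and interferon-stimulated genes (6 rose) passed by camera, but not with an estimated correlation (adjusted p = 0.296, 0.189 and 0.183). The unfolded protein response also lost its call without DMSO array 2, and the interferon-stimulated genes without DMSO array 1 or 4 or 0.5 µM array 3. Of 28 inflammatory genes 6 rose and 2 fell (camera adjusted p = 0.0564, adjusted p = 0.34 with an estimated correlation). Adjusted over the list alone, 33 p53 targets, 20 histones, 12 immediate early genes, 4 receptor targets and 34 oxidative phosphorylation genes rose. On the same basis 48 G2/M, 30 G1/S, 13 Fanconi anaemia and recombination and 7 hypoxia genes fell, and excision repair had 3 each way.

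Limma called 2002 genes at 0.5 µM, 1075 higher and 927 lower. The lower genes were the more numerous after median centring (939 and 970), with only these groups in the fit (1890 and 2226), with a 1.5-fold minimum (711 and 755) and without 1 µM arrays 2 and 3 (2044 and 2346). The count was 4116 with only these groups in the fit and 938, 1042 and 986 without 0.5 µM arrays 1, 2 and 3, and 1308 without DMSO array 3. The poly-A control transcript dap read 8.55 to 8.74 in the 0.5 µM arrays, above the 6.33 to 7.33 of DMSO, and the 3' minus 5' difference of ACTB, a sign of RNA quality, 0.633 to 0.713 against 0.298 to 0.620.

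At 1 µM, histone genes were higher than in DMSO. Of 51 mitotic genes 47 fell, though the test of this list gave adjusted p = 0.0567 with an estimated correlation. TTK fell by 3.46 ± 0.16 (SE; adjusted p = 2.43e-07) and CCNB1 by 3.79 ± 0.49 (adjusted p = 6.25e-04). SAT1 rose by 3.16 ± 0.21 (adjusted p = 5.29e-06), ATF3 by 3.76 ± 0.34 (adjusted p = 5.69e-05) and GDF15, a stress-induced cytokine, by 1.87 ± 0.20 (adjusted p = 2.14e-04). IL11, a cytokine of the interleukin 6 family, rose by 2.13 ± 0.26 (adjusted p = 5.06e-04). RNA45SN5 rose by 3.92 ± 0.52 (adjusted p = 7.42e-04). The 28S control probe set read 7.93, 8.80, 7.70 and 7.76 in 1 µM arrays 1, 2, 3 and 4. In DMSO arrays 1, 2, 3 and 4 it read 8.32, 6.42, 6.53 and 6.17. Thus 3 of 4 arrays at 1 µM lay inside the DMSO range, but its upper end was DMSO array 1 alone. Against the DMSO array of the same number, 28S was lower in array 1 and higher in arrays 2, 3 and 4. The 7 genes named in this paragraph also passed with only the 1 µM and DMSO arrays in the fit.

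Of 51 G2/M genes, 47 fell and 0 rose at 1 µM (mean -2.12; camera adjusted p = 1.11e-49, but adjusted p = 0.0567 with an estimated correlation), and 37 fell with only these groups in the fit. Of 45 G1/S genes, 26 fell (mean -1.08; adjusted p = 0.0831 with an estimated correlation), or 14 with only these groups in the fit. Of 42 histone genes, 14 rose and 0 fell (mean 0.59; adjusted p = 0.0061 with an estimated correlation), or 2 with only these groups in the fit, H1-2 among them at 2.17 ± 0.22. Of the lists tested at 1 µM, only the histones passed with an estimated correlation. By fry, which does not compare a list with other genes, more lists passed in the model over all arrays. Among them were the G2/M, Fanconi anaemia and recombination, G1/S, inflammatory and p53 lists (fry adjusted p = 4.74e-05, 6.14e-05, 3.88e-04, 5.68e-04 and 0.025). Excision repair and translesion synthesis did not pass (fry adjusted p = 0.584 and 0.0775). Of 28 inflammatory genes, 8 rose and 1 fell (mean 0.72; adjusted p = 0.0966 with an estimated correlation), or 2 and 0 with only these groups in the fit. CXCL8, the neutrophil chemokine interleukin 8, rose by 4.54 ± 0.76 (adjusted p = 0.0032, and 0.0567 with only these groups in the fit); array 1 read 4.41 and the others 8.64 to 8.80. Of 24 Fanconi anaemia and homologous recombination genes 10 fell (mean -0.76; adjusted p = 0.0567 with an estimated correlation), or 4 with only these groups in the fit. Of 25 genes of the unfolded protein response 9 fell (mean -0.54; adjusted p = 0.113 with an estimated correlation), or 1 with only these groups in the fit. Of 86 oxidative phosphorylation genes 34 rose and 1 fell (adjusted p = 0.202 with an estimated correlation), or 2 and 0 with only these groups in the fit, and of 12 receptor targets 3 rose (adjusted p = 0.0694 with an estimated correlation), or 0. The receptor targets CYP1A1 and AHRR, called at 0.5 µM, did not pass at 1 µM (limma adjusted p = 0.174 and 0.478). PTGS2, which is also on the inflammatory list, was called at 1 µM (limma adjusted p = 0.00625, and 0.0822 with only these groups in the fit). The immediate early genes did not pass (camera adjusted p = 0.116), nor did cholesterol synthesis and interferon-stimulated genes (camera adjusted p = 0.481 and 0.382) or the hypoxia genes, of which 2 rose and 2 fell, or 0 and 0 with only these groups in the fit. Adjusted over the list alone, 49 G2/M, 33 G1/S, 15 Fanconi anaemia and recombination and 10 unfolded protein response genes fell, and 17 histones, 10 inflammatory genes and 21 p53 targets rose.

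The p53 targets differed between the 1 µM arrays. Of 46 targets, 15 rose and 0 fell (mean 0.54; camera adjusted p = 1.11e-07, but adjusted p = 0.319 with an estimated correlation), and 4 rose with only these groups in the fit. The mean shift of the list from DMSO was 0.917, 0.106, 0.074 and 1.07 in arrays 1, 2, 3 and 4, against an SD of 0.080 between the 3 arrays at 0.5 µM. CDKN1A did not pass (0.54 ± 0.25 SE, adjusted p = 0.182), with an SD of 0.68 at 1 µM. The shift of the G2/M list lay -9.03, -11.9, -6.05 and -10.7 DMSO SDs from the DMSO mean in the same 4 arrays. GAPDH, a glycolytic enzyme often used as a reference, differed by 0.11 ± 0.07 (adjusted p = 0.342). The 3' minus 5' difference of ACTB was 0.754 and 0.712 in arrays 1 and 4, above the 0.298 to 0.620 of DMSO. In arrays 2 and 3 it was 0.432 and 0.485, inside that range but above the 0.298 and 0.422 of DMSO arrays 2 and 3.

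Limma called 2144 genes at 1 µM, 911 higher and 1233 lower, but 247 with only the 1 µM and DMSO arrays in the fit. The fit of all arrays shares 1 spread with the much tighter groups and estimates it from more arrays. How much each adds to the larger count was not tested. In simulated arrays that kept each group's own spread, with 200 of 19775 genes changed, that fit called 205.4 to 249.4 unchanged genes per draw. They were 56 to 66% of its calls there, a share that depends on how many genes were changed and does not carry over to the 2144. Of the 71 genes named by rule and called at 1 µM, 29 passed with only these groups. The count was 1074 and 1331 without DMSO arrays 3 and 4, and 4520, 1382 and 3698 without 1 µM arrays 1, 2 and 4.

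**Figure D1:**
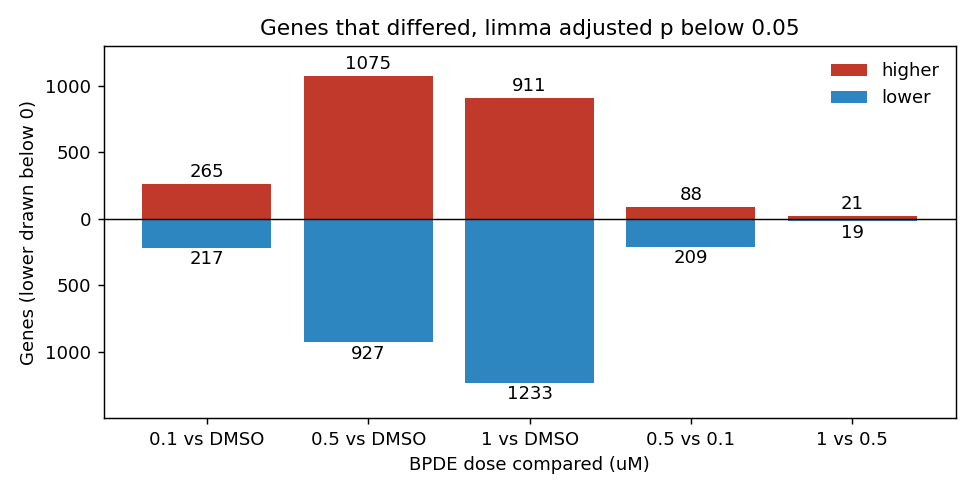
Number of genes higher (above 0) and lower (below 0) in each comparison, limma with all 14 arrays, by the BPDE doses compared in µM. The bars reach 265 and 217 at 0.1 µM, 1075 and 927 at 0.5 µM and 911 and 1233 at 1 µM, and the 1 µM count was 247 in all with only its own groups in the fit.

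**Figure D2:**
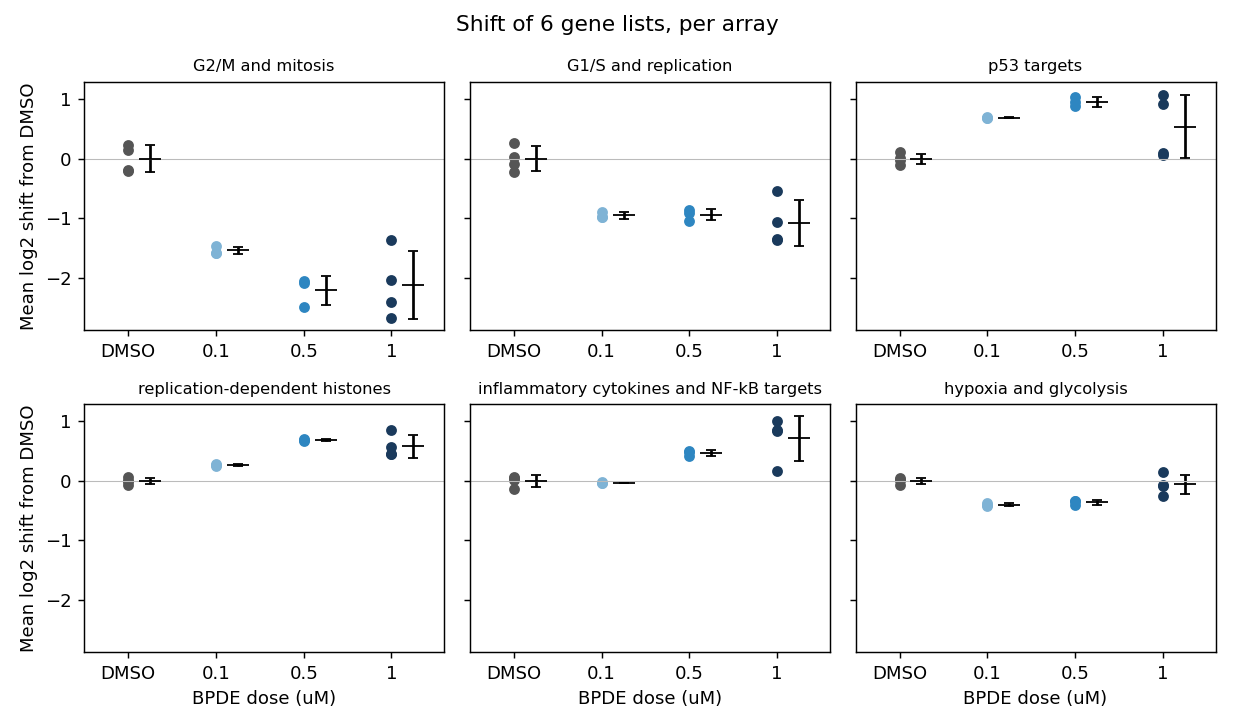
Mean log2 shift of the members of 6 gene lists from the DMSO mean against BPDE dose in µM, 1 point per array, with the mean and SD of each group beside the points. The G2/M list lies below DMSO at every dose, and the p53 targets in the 1 µM arrays range from 0.074 to 1.07.

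**Figure D3:**
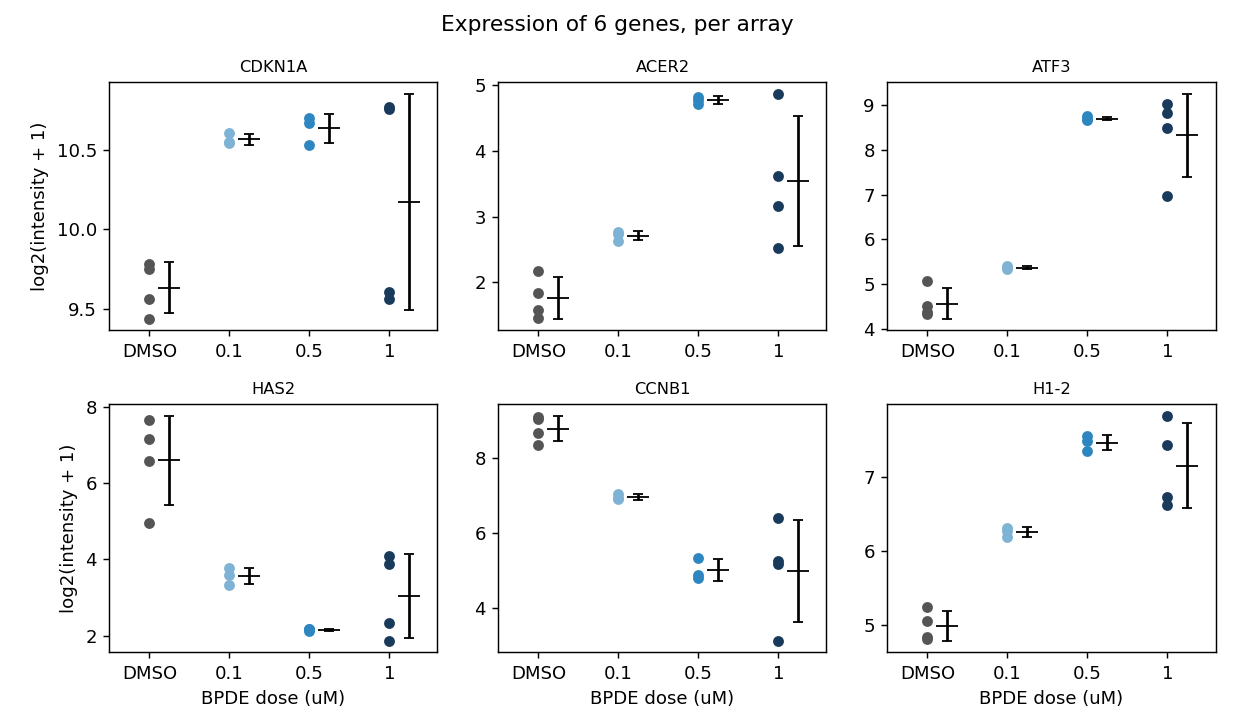
Level of 6 genes in log2(intensity + 1) against BPDE dose in µM, 1 point per array, with the mean and SD of each group beside the points; each panel has its own axis. CCNB1 and HAS2 are lower and ATF3 and H1-2 higher at 0.5 and 1 µM, and CDKN1A in the 1 µM arrays has an SD of 0.68.

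Markers of other cell types were tested at each dose. At 1 µM, epithelial, endothelial and smooth muscle markers did not pass (camera adjusted p = 0.219, 0.959 and 0.831). The 13 leukocyte markers had a mean change of 0.18 (camera adjusted p = 0.0443, adjusted p = 0.248 with an estimated correlation) with 0 members called, or 1 with the replicate number as a block, CD74 (log2 change 0.52, adjusted p = 0.048). The camera adjusted p of the leukocyte list rose to 0.0804 at most when DMSO array 3 or 4 or 1 µM array 1, 2 or 3 was left out. At 0.5 and 0.1 µM none of these 4 lists passed, with camera adjusted p from 0.129 to 0.93. Single members were called by limma. The epithelial marker MUC1 was higher at 1 µM (adjusted p = 0.0371, and 0.18 with only these groups in the fit). The smooth muscle markers CNN1 and CALD1 were higher at 0.5 µM (adjusted p = 0.0235 and 0.0325). At 0.1 µM CALD1 was higher and the endothelial marker TIE1, at a low level, was lower (adjusted p = 0.0315 and 0.0277). The fibroblast markers did not pass at 1, 0.5 or 0.1 µM (camera adjusted p = 0.711, 0.293 and 0.599). Of these 15 markers 4 fell at 0.5 µM, COL1A1 and COL3A1 among them, and 1 rose, the calcium-binding protein S100A4, by 2.13 ± 0.23.

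The doses shared many of their calls. In the same direction, 1266 genes were called at both 1 and 0.5 µM (566 higher, 700 lower), 269 at 1 and 0.1 µM and 347 at 0.5 and 0.1 µM. Opposite calls numbered 2, 12 and 4. All 3 doses shared 258 genes, 114 higher and 144 lower. The comparisons use the same DMSO arrays, and unchanged groups simulated against shared controls gave 0.02, 0 and 0.02 shared genes on average over 50 draws. Independent lists would share 49.5 higher and 57.8 lower, 12.2 and 13.5, and 14.4 and 10.2 genes. With the controls split between the comparisons, 355 to 483, 27 to 100 and 59 to 148 genes were shared. The covariance of the changes was 0.159, 0.0477 and 0.0825 against simulated values of 0.0208, 0.0207 and 0.0207. Across genes, which are not independent replicates, the correlation of the changes was 0.819, 0.347 and 0.618 against simulated values of 0.464, 0.462 and 0.427. With the controls split it ran from 0.618 to 0.753, 0.112 to 0.31 and 0.401 to 0.484. The simulated arrays had 1 pooled spread per gene in every group and no pairs, while the real spreads differed greatly. The simulated values therefore need not match what shared controls alone would give in these groups, and no conclusion is drawn from them. With only the groups compared in each fit the shared counts were 240, 166 and 990.

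From 0.1 to 0.5 µM, the stress-induced ATF3 rose and the mitotic kinase TTK fell further. ATF3 was higher at 0.5 µM by 3.33 ± 0.40 (SE; adjusted p = 0.00189), and TTK and NCKAP5 were lower by log2 changes of -2.26 ± 0.18 (adjusted p = 1.99e-04) and -2.73 ± 0.29 (adjusted p = 8.74e-04). RNA45SN5 was higher by 3.63 ± 0.60 (adjusted p = 0.0134, up to 0.0754 with 1 array left out). Limma called 297 genes, 88 higher and 209 lower, and 7562 with only these tight groups in the fit. Leaving out 1 of the 0.1 or 0.5 µM arrays gave 40 to 63, and leaving out DMSO array 3 or 1 µM arrays 4, 2 and 1 gave 171, 507, 640 and 938.

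Between 0.5 and 1 µM, AK4 and the chemokine CCL2 were higher at 1 µM by 2.78 ± 0.26 and 2.42 ± 0.24 (SE; adjusted p = 0.00158 each), and MMP10, a matrix metalloproteinase, fell by 2.21 ± 0.26 (adjusted p = 0.0026). Against DMSO, AK4 and CCL2 fell by 2.35 and 1.88 at 0.5 µM (adjusted p = 1.96e-04 and 4.90e-04), MMP10 was called higher (adjusted p = 5.97e-05), and at 1 µM the log2 changes of the 3 genes were 0.43, 0.53 and 0.49 (adjusted p = 0.28, 0.147 and 0.208). In each of these genes the 0.1 and 0.5 µM arrays lay outside the range of the DMSO and 1 µM arrays. Limma called 40 genes, 21 higher and 19 lower, of 1498 at an unadjusted p under 0.05. The lower genes were the more numerous with a pseudocount of 16 (25 and 42), without 1 µM array 2, 3 or 4 (20 and 24, 20 and 23, 103 and 170) and without arrays 2 and 3 together (481 and 487). With only these groups in the fit limma called 0 (871 at an unadjusted p under 0.05), and with the replicate number as a block 72. The count was 10, 9 and 12 without 0.5 µM arrays 1, 2 and 3, 21 without any 0.1 µM array, 23 without DMSO array 3, and 107 and 273 without 1 µM arrays 1 and 4.

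Along a straight line in dose, CXCL8 had the steepest rise, 5.11 ± 0.80 log2 units per µM (SE; adjusted p = 0.00447), followed by RNA45SN5, ATF3 and PTGS2, the inducible cyclooxygenase, at 3.99 ± 0.78, 3.83 ± 0.64 and 3.49 ± 0.56. CCNB1, TTK and KIF11, a spindle motor, had slopes of -3.42 ± 0.67, -3.27 ± 0.49 and -3.10 ± 0.52. Limma called 2547 genes, 894 rising and 1653 falling with dose; after median centring the split was 614 and 1835. The count ran from 786 without 1 µM array 2 to 4904 without 1 µM array 1, and was 1387, 1410 and 1677 without DMSO arrays 3, 4 and 2, 1524, 1590 and 1608 without 0.1 µM arrays 1, 2 and 3, and 1487 and 4095 without 1 µM arrays 3 and 4.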

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

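The tests of a shared batch, and of the gene lists among its genes, were chosen after the result was seen. Of 350 sets of 4 arrays (DMSO or 1 µM, each for a named gene or a list), 15 had 1 array far from the other 3; chance gives about 1 in 20.

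In DMSO array 1, the Wnt, Notch and Hedgehog list shifted by -0.153 (others 0.035 to 0.062), the smooth muscle markers by -0.201 (others 0.042 to 0.091), and CNN1 read 7.35 (others 7.94 to 8.01). In DMSO array 3, EZH2 read 5.59 (others 5.07 to 5.09) and RPS27L 10.74 (others 10.86 to 10.88). In 1 µM array 1, CXCL8 read 4.41 (others 8.64 to 8.80), PTGS2 2.82 (others 6.10 to 6.25), GADD45A 9.56 (others 10.63 to 10.76), NDUFA5 7.57 (others 8.09 to 8.19) and PMAIP1 8.53 (others 10.14 to 10.26). In 1 µM array 2, SMTN read 5.61 (others 7.00 to 7.15). In 1 µM array 3, DTL read 5.82 (others 3.65 to 3.98) and GINS2 5.97 (others 4.42 to 4.62). In 1 µM array 4, AKR1B10 read 5.06 (others 2.91 to 3.12) and CYP1B1 6.54 (others 4.43 to 4.66).

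Control probe sets outside the gene comparisons also stood above DMSO. At 0.5 µM, the 3' minus 5' log2 difference of ACTB averaged 0.677 (DMSO 0.298 to 0.620) and the 28S ribosomal RNA control 9.68 (DMSO 6.17 to 8.32). The poly-A control transcript dap averaged 8.09 at 0.1 µM and 8.62 at 0.5 µM (DMSO 6.33 to 7.33).

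A pattern shared by 0.1 and 0.5 µM but not 1 µM was also seen, in fewer genes than one that follows dose. Of 6938 genes with a mean log2 level of at least 5, 112 had all 6 arrays of 0.1 and 0.5 µM outside the 8 others, against 4.6 by chance; the grouping of 0.5 with 1 µM, which follows dose, separated 527 and that of 0.1 with 1 µM separated 6 (4 by chance for each). The 112 genes held 5 of 22 hypoxia and glycolysis genes (BNIP3, NDRG1, PDK1, ALDOC and PGK1; 0.36 in proportion, Fisher's exact test, one-sided, p = 2.12e-05, adjusted over the lists 4.88e-04). This list had already passed by camera at 0.1 and 0.5 µM but not at 1 µM in the same arrays. The test therefore restates that result and is no separate support, and it treats genes that move together as independent. A batch shared by the 0.1 and 0.5 µM arrays could give the pattern, as could a response to lower doses. They cannot be told apart: each dose lies wholly inside one side, and the control transcript dap, though higher at 0.1 and 0.5 µM, reached 8.44 in 1 µM array 2. The labels give no batch, though the 0.1 and 0.5 µM samples were numbered apart from the others in the deposit.

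Other splits of the arrays were counted for each comparison. At 1 µM, 1 of 35 splits, the real one, gave as many genes (2144; highest other 1254, which put 1 µM array 4 with DMSO arrays 2, 3 and 4 and so kept pairs together). With the numbers taken as pairs, only 8 splits part every pair, too few for a share under 0.05 (highest other 7). At 0.5 µM chance is argued against (1 of 35 splits, the smallest share possible, with 2002 against 218). The shares were not adjusted over the comparisons, and splits cannot separate dose from a batch of the same arrays. For the trend chance is argued against only over shuffles that ignore the pairs (1 of 100, with 2547 against 213), and none that keep them were run. At 0.1 µM chance is argued against over 35 splits (1 of 35, with 482 against 8). If its numbers pair, the splits that part every pair are too few for a share under 0.05. For 0.5 against 0.1 µM, 10 splits are too few for a share under 0.05 (297; highest other 0). For 1 against 0.5 µM, 4 of 35 splits gave as many (40; highest other 2350), so chance cannot be excluded; the 2350 came from a split that put 1 µM arrays 1 and 4 with 0.5 µM arrays 2 and 3, which points to a structure of the samples other than dose.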

How the results depend on the processing

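Pseudocounts of 0 and 16 and the removal of 1 µM arrays 2 and 3 were added after seeing the data. Except where an alternative itself means fewer arrays, fewer genes or a stricter threshold, the cause was not tested. With only the groups compared in the fit, genes called were 247 (1 µM), 4116 (0.5 µM), 1589 (0.1 µM), 7562 (0.5 against 0.1 µM) and 0 (1 against 0.5 µM), with 240, 166 and 990 shared by 1 and 0.5, 1 and 0.1, and 0.5 and 0.1 µM. Array weights gave 5623, 2968, 7817 and 114 for 0.5 µM, 0.1 µM, 0.5 against 0.1 and 1 against 0.5 µM, 6483 for the trend, and 2164, 763 and 1937 shared. Without 1 µM arrays 2 and 3 the counts were 2101 at 1 µM, 4390 at 0.5 µM, 1722 at 0.1 µM, 2710 for 0.5 against 0.1, 968 for 1 against 0.5 µM and 899 for the trend, with 786 shared by 1 and 0.1 and 1086 by 0.5 and 0.1 µM. Every probe set as a unit gave 3402 (1 µM), 3411 (0.5 µM), 74 (1 against 0.5 µM) and 3930 (trend), and 2024 shared by 1 and 0.5 µM; a 1.5-fold minimum gave 1401 at 1 µM and 841 shared with 0.5 µM. A pseudocount of 16 gave 448 for 0.5 against 0.1 µM and 67 for 1 against 0.5 µM. With the replicate number as a block, 1 against 0.5 µM had 72 genes; no other count moved by over 1.5 times (2520 at 1 µM), while 4 lists and 11 named genes changed their call, among them CXCL8 and FOS for 0.5 against 0.1 µM (adjusted p = 0.0511 and 0.0646), and the aryl hydrocarbon receptor targets, SEMA6D and FOSL2 at 0.1 µM (adjusted p = 0.0622, 0.0617 and 0.0675); translesion synthesis at 1 µM gained a call (adjusted p = 0.0368). At 0.5 µM, where the numbers were not taken as pairs, the inflammatory genes gained a call and the unfolded protein response lost one (adjusted p = 0.0324 and 0.0562).

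Of the lists, 15, 15 and 12 passed at 1, 0.5 and 0.1 µM. With an estimated correlation 1, 7 and 6 did, and with the filter on dim genes 9 at 1 µM and 9 at 0.5 µM. By fry, 74 list results over the doses stayed as by camera, 5 lost their call and 2 gained one. The p53 targets passed by fry at 1, 0.5 and 0.1 µM (fry adjusted p = 0.025, 0.00281 and 0.0152). Without probe sets that can match several transcripts, 9 lists passed at 1 µM, 26 genes were called for 1 against 0.5 µM and 176 shared by 1 and 0.1 µM. That setting also turned the sign of the heat shock list at 1 µM (0.028; 0.064 without 1 µM arrays 2 and 3), NDUFA2 at 1 µM (-0.011), SC5D at 0.1 µM (-0.031) and TIE1 at 0.1 µM (0.024).

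With 1 array left out, counts ran from 1074 to 4520 (1 µM), 938 to 2844 (0.5 µM), 79 to 771 (0.1 µM), 40 to 938 (0.5 against 0.1 µM), 9 to 273 (1 against 0.5 µM) and 786 to 4904 (trend). Shared counts ran from 678 to 2082, 43 to 390 and 68 to 530, and lists from 14 to 17, 14 to 17 and 10 to 13. Of the called named genes, 55 of 71 at 1 µM, 56 of 78 at 0.5 µM and 14 of 51 at 0.1 µM passed in each of these fits. Low signal over background limits dim genes, whose changes the added 1 shrinks.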

Other observations

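The tests of long against short genes were planned before their results were seen. The test of p53 targets by gene length was rewritten after its values were seen and then set aside.

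Single genes of other lists passed the test. At 1 µM, EZH2, a histone methyltransferase, and SUV39H1 and SUV39H2, which methylate histone H3, fell by 1.44 ± 0.26, 1.13 ± 0.14 and 1.15 ± 0.17 (SE; adjusted p = 0.00445, 5.52e-04 and 0.00139); EZH2 did not pass with only the 1 µM and DMSO arrays in the fit (adjusted p = 0.0724). Of 42 chromatin modifiers 6 fell and 0 rose (adjusted p = 0.0999 with an estimated correlation), or 2 fell with only these groups in the fit. The chromatin list shifted by -0.163, -0.957, -0.753 and -0.305 in 1 µM arrays 1, 2, 3 and 4, furthest in arrays 2 and 3. HSPD1 and HSPE1, mitochondrial chaperones, fell by 0.73 ± 0.12 and 1.12 ± 0.21 at 0.5 µM, while HSPB8, a small heat shock protein, rose by 1.06 ± 0.22. VLDLR, a lipoprotein receptor, fell by 1.86 ± 0.24 at 0.5 µM. Of 15 translesion synthesis genes, which copy past adducts, 3 fell and 0 rose at 0.5 µM (camera adjusted p = 0.537). At 1 µM 2 fell and 0 rose (mean -0.35, camera adjusted p = 0.0611, and 0.0368 with the replicate number as a block), or 0 with only these groups in the fit. The translesion list shifted by -0.282, -0.732, -0.451 and 0.048 in 1 µM arrays 1, 2, 3 and 4, so array 4 did not fall.

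The remaining lists, with camera adjusted p at 1, 0.5 and 0.1 µM, were NRF2 targets (0.00556, 0.0509 and 0.424), heat shock proteins (0.0187, 0.375 and 0.832), apoptosis genes (0.655, 0.537 and 0.24), extracellular matrix genes (0.475, 0.00295 and 0.00665), ribosomal proteins (1.11e-07, 1.39e-04 and 0.103) and Wnt, Notch and Hedgehog genes (0.0101, 0.115 and 0.53). None of these 6 passed with an estimated correlation at any dose (adjusted p = 0.0831 to 0.93). With 1 array left out, camera adjusted p became 0.179 for heat shock proteins at 1 µM (without 1 µM array 2) and 0.165 for extracellular matrix genes at 0.1 µM (without DMSO array 2). It fell to 0.0419 for extracellular matrix genes at 1 µM (without DMSO array 1), and at lowest to 0.00407 and 0.0486 for NRF2 targets at 0.5 and 0.1 µM. The heat shock list at 0.1 µM had a mean change of 0.05 while its test pointed down.

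Long genes read lower relative to short genes at 0.5 and 1 µM. Among genes with a mean log2 level of at least 5, the median of the 1734 longest (at least 71.4 kb) minus that of the 1734 shortest (at most 12.5 kb) differed from DMSO by -0.239 at 1 µM (SD 0.109, n = 4), -0.276 at 0.5 µM (SD 0.011, n = 3) and 0.087 at 0.1 µM (SD 0.017, n = 3; DMSO SD 0.031, n = 4; exact permutation p = 0.0286 each, two-sided, adjusted 0.0286, the smallest these groups can give). Over all genes the differences were -0.109, -0.109 and 0.024 (exact permutation p = 0.0286, 0.0286 and 0.371, two-sided, adjusted 0.0429, 0.0429 and 0.371). With swaps only within the 4 pairs of DMSO and 1 µM arrays the exact p at 1 µM was 0.125, the smallest 16 swaps can give, so that the 1 µM difference does not pass when paired. If the 0.1 µM numbers pair too, the exact p there is 0.25, the smallest 8 swaps can give, and that difference does not pass either. Within 3 bands of the mean level all 12 values of the 1 µM arrays, the same 4 arrays in each band, lay below all 4 DMSO arrays. This argues against a difference in signal level between the bands as the whole of the shift. Long and short genes were not matched in level within a band, so a level difference there stays open. Blocked transcription at adducts, which would lower long genes more, stays open as a hypothesis: that 4 of 4 arrays at 1 µM lay below all DMSO arrays is the shift itself and does not separate this from other explanations. RNA degradation or labelling also stays open, because 2 of 8 values of the 3' minus 5' difference of GAPDH and ACTB at 1 µM lay outside the DMSO range. Both were ACTB, which read 0.754, 0.432, 0.485 and 0.712 in arrays 1, 2, 3 and 4. In DMSO arrays 1, 2, 3 and 4 ACTB read 0.620, 0.298, 0.422 and 0.320, so it was higher at 1 µM in all 4 pairs. GAPDH was lower at 1 µM in pairs 1, 2 and 3 and higher in pair 4. Long minus short was -0.162, -0.392, -0.244 and -0.159 in 1 µM arrays 1, 2, 3 and 4. Among the 1 µM arrays ACTB was therefore not highest where the shift was largest. At 0.5 µM, where long genes were also lower, the ACTB values of 0.686, 0.713 and 0.633 all lay above the DMSO range of 0.298 to 0.620. At 0.1 µM, where long genes were not lower, they were 0.595, 0.523 and 0.715.

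The p53 targets are given by gene length and array as values only. Tests of 2 explanations for their differences between the 1 µM arrays, an exchange or mixing with DMSO samples and a loss of long genes, were run and set aside, because they compared arrays chosen by their outcome. The first had read the G2/M shift of -6.05 DMSO SDs in array 3 against mixing, and the second a short minus long difference of 0.096 in array 3, just above the DMSO maximum of 0.081, as favouring a loss of long genes. Neither is used as evidence here. At 1 µM, the 23 targets of at most 28 kb shifted by 0.929, 0.307, 0.122 and 1.02 in arrays 1, 2, 3 and 4, and the 23 longer ones by 0.904, -0.094, 0.026 and 1.13. In DMSO the shorter ones ranged from -0.086 to 0.148 and the longer ones from -0.118 to 0.067.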
